A study of Mus musculus with 56 samples.

How the data were processed

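Whole adrenal glands of C57BL/6J mice were measured by bulk RNA sequencing, with libraries made from poly(A) RNA by a directional kit, per the labels' protocols. The 56 samples formed 14 groups of 4 animals: females at 6, 9 and 12 weeks and males at 4, 6 and 9 weeks, each as conditional knockout (cKO; floxed Znrf3 with SF1-Cre) and as littermate control without Cre. The other groups were male cKO animals at 9 weeks that had been castrated or sham-operated at week 4. The surgery series carried mixed reporter alleles (none, eYFP or mTmG). Sham animals all had the same replicate number in the labels, so they were numbered in accession order as names only.

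The deposited values are raw gene-level counts in 3 tables, 1 for females, 1 for males and 1 for the surgery series, with whole numbers per Ensembl gene identifier that are not normalised. Per the submitters' processing notes, STAR 2.7.6a, cutadapt 1.16, RSEM 1.6.3, DESeq2 1.30.1 and featureCounts were used with the GRCm38 build, with no role or order stated for each. The version of featureCounts is not given in the sources used here. How reads of near-identical paralogs and of overlapping genes were split is likewise not given, so values of gene families such as Akr1c and Cyp11b carry that uncertainty. The tables of females and males share 55487 gene identifiers. The surgery table has 55414, of which 3024 are absent from the others, so it was counted with another annotation release. Of its identifiers 93.99% against 99.38% in the others matched a symbol in the GENCODE M21 annotation of GRCm38, which supplied gene names and positions. In the library with the lowest share, identifiers with a symbol held 99.94%, 99.93% and 93.91% of counts in the 3 tables. In sham replicate 1 a single identifier without a symbol held 6.01% of counts. No row lacked an identifier, and 0 columns were left unmapped. Because the sexes lie in different tables, levels were never compared across tables, only genotype effects.

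Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr at a minimum count of 10, which left 18645 genes in females, 17086 in males and 16961 in the surgery series. It left 17681 and 17824 in the joint fits of both sexes at 6 and 9 weeks. Libraries were scaled by TMM factors. The main test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p under 0.05. All groups of a sex entered 1 fit, so that they share an estimate of the spread (common biological coefficient of variation 0.179 in females, 0.181 in males and 0.221 in the surgery series). Changes of the genotype effect with age were interaction contrasts in the same fits, and differences between the sexes were interaction contrasts with an effect of sex, which also absorbs the table. Standard errors of log2 fold changes are approximate, derived from the fold change and its F statistic. Levels are TMM-normalised CPM (counts scaled to the same library total), given as mean ± SD of 4 animals; log2 CPM used a prior count of 2. Alb, Th and shares of counts in single libraries are CPM or percentages of the library total.

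A total of 22 gene lists were tested: Wnt/beta-catenin targets, zona glomerulosa, steroidogenesis and zona fasciculata, X-zone, gonad-type steroidogenic genes, cholesterol synthesis and uptake, cell cycle and DNA replication, p53 targets and CDK inhibitors, senescence-associated secretory genes, interferon-stimulated genes, macrophages and monocytes, phagocytosis and lysosome, antigen presentation and dendritic cells, T and NK cells, B and plasma cells, neutrophils, adrenal medulla, Schwann cells, endothelium, fibroblasts with capsule and extracellular matrix, adipose tissue and erythrocytes. The test was camera at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Called members were counted over all genes tested and again adjusted over the list alone.

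Genes named in the text follow a fixed rule. It names a set of genes looked at in each comparison (Znrf3, Rnf43, Axin2, Lef1, Cdkn1a, Cdkn2a, Mki67, Star, Cyp11b1, Cyp11b2, Nr5a1, Cd68, Trem2 and Akr1c18, with others not reported here). To these it adds the 5 largest rises and 5 largest falls among called genes with an average log2 CPM of at least 1, where all 4 libraries of one group lay beyond all 4 of the other (4 and 4 without that condition for changes with age and sex). From each list it adds at most 4 genes with the smallest p (2 for changes with age and sex). The text leaves out some genes that the rule allows. Single effects of a gene quoted beside its sex difference, such as those of Mgat4c in males, come from the table of all genes.

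Tests were repeated, each where it applies, with DESeq2 1.42.0, with relative log expression scaling, without the low-count filter, with a filter of CPM 5 in 4 libraries, with fits limited to the groups compared, with replicate numbers as a block, with the range of the male library numbers in the sample titles (up to 24 or above) as a covariate, with the reporter allele as a covariate, with all 48 libraries of the genotype comparisons in 1 fit, and without each library in turn. These alternatives, the comparisons, the gene lists and the rule for named genes were fixed before the data were examined. Chosen after seeing the data were the comparisons of the first with the last age in each sex, the fits with library numbers up to 24 or above 24 only, a fit of the surgery series scaled by library totals, and fits without the libraries with a high level of the liver transcript Alb (female cKO replicate 2 at 12 weeks, and male cKO replicates 2 at 4 weeks, 2 at 6 weeks and 3 at 9 weeks).

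The edgeR gene test was tried on simulated data drawn from the genes' mean levels and the real library sizes. List tests and splits were not simulated. The changed genes were few and lay in a single group. The real genotype and castration comparisons called many more genes, so recovery there may differ. Of genes changed 2-fold, 62.7% were recovered for females at 6 weeks, 64.2% for males at 9 weeks, 49.3% for the change from 6 to 9 weeks in males, 52.2% for the sex difference at 9 weeks and 55.2% for castration (67 changed genes each). Of genes changed 4-fold, in the same order, the shares were 83.3%, 93.9%, 71.2%, 81.8% and 95.5% (66 each), and there were 5, 5, 2, 6 and 8 false calls. Depth limits low genes most in males, where the shallowest library held 12.4M counts. No library held sex-linked transcripts that differed from its labelled sex, and no libraries agreed within sampling noise.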

Results

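Adrenal glands of C57BL/6J mice were profiled by poly(A)-selected, strand-directional RNA sequencing in 56 samples that fell into 14 groups of 4 animals. Floxed Znrf3 was combined with SF1-Cre, a Cre driver active in steroidogenic cells of the adrenal cortex, and these conditional knockout (cKO) glands were set against glands of littermates without Cre. Female glands came from animals aged 6, 9 or 12 weeks, male glands from animals aged 4, 6 or 9 weeks. A separate male series at 9 weeks compared cKO animals castrated at week 4 with cKO animals given sham surgery at the same age, 4 animals each. Per the series design text, the question was which mechanisms accompany a switch from enlargement of the gland to its later regression. Total counts per library ran from 35.7M to 51.6M in females (median 41.6M), from 12.4M to 35.5M in males (median 17.9M) and from 25.1M to 42.4M in the surgery series (median 33.6M).

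Znrf3 encodes a membrane ubiquitin ligase that removes Wnt receptors from the cell surface (ENSMUSG00000041961, GRCm38 chromosome 11, 5276324 to 5444847). It was checked in each group before any other gene. Its total gene-level count was higher, not lower, in libraries labelled cKO. It was at 76.7 ± 19.5 against 36.6 ± 2.85 CPM in females at 6 weeks (mean ± SD, n = 4 per group), 74.4 ± 8.67 against 35.8 ± 3.2 at 9 weeks and 74.9 ± 8.56 against 34.3 ± 2.76 at 12 weeks. In males the levels were 52.1 ± 6.77 against 32.3 ± 7.07 CPM at 4 weeks, 40.4 ± 4.52 against 28.9 ± 2.63 at 6 weeks and 46.5 ± 4.7 against 32.3 ± 4.62 at 9 weeks. The 4 libraries labelled cKO lay above the 4 controls in each of these comparisons. Each rise passed edgeR's quasi-likelihood test, with a log2 fold change of 1.13 ± 0.13 (SE) at its largest in females at 12 weeks (adjusted p = 1.07e-06) and 0.49 ± 0.13 at its smallest in males at 6 weeks (adjusted p = 0.0114). With library numbers up to 24 only, the log2 fold change was 0.29 at 4 weeks, where a single control is left, the one with the highest Znrf3 level of the 4, and 0.40 at 9 weeks. With the library number range as a covariate it was 0.37 at 6 weeks (adjusted p = 0.23), and none of these passed the threshold. Castrated and sham-operated cKO glands held 61 ± 4.21 and 50.9 ± 8.29 CPM (log2 fold change 0.26 ± 0.13, adjusted p = 0.126). A count summed over the whole gene cannot show which part was deleted, so these values do not check the deletion and the labels are used as given.

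In female glands at 6 weeks, genes of 3 parts of the gland were strongly lower in the cKO. Among them were genes of the chromaffin cells of the adrenal medulla. Chga, which encodes the granule protein chromogranin A (chromosome 12, 102554969 to 102565028), fell 13.7-fold (116 ± 29.4 against 1582 ± 182 CPM, mean ± SD, n = 4 per group; log2 fold change -3.77 ± 0.28 SE). Genes of the outer cortical zone, the zona glomerulosa, fell as well. The aldosterone synthase gene Cyp11b2 (chromosome 15, 74851010 to 74856318) went from 358 ± 80.9 to 33.2 ± 10.2 CPM. The potassium channel gene Kcnk9 fell 9.87-fold (-3.30 ± 0.19), the angiotensin receptor gene Agtr1b fell 12-fold (-3.58 ± 0.22), and Shh, which marks progenitors of the outer cortex, fell 5.1-fold (-2.35 ± 0.24). Akr1c18, a progesterone-metabolising enzyme gene that marks the X-zone of the inner cortex (chromosome 13, 4132615 to 4150654), went from 1788 ± 943 to 19.4 ± 14.2 CPM, and Pik3c2g, another X-zone marker, from 224 ± 57.9 to 4.81 ± 4.75 CPM. The largest rise outside the fixed lists was that of Mgat4c, a glycosyltransferase gene (chromosome 10, 101681487 to 102391469), at 569 ± 149 against 22.3 ± 20.8 CPM. Scube1, a secreted EGF-domain protein gene, rose 8.16-fold (3.03 ± 0.29), while Gjb2, a gap junction gene, and Gsta3, a glutathione transferase gene, fell 34-fold and 26.5-fold (-5.09 ± 0.46 and -4.73 ± 0.46).

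Across the gene lists fixed beforehand, all 12 medulla genes were lower in females at 6 weeks (median log2 fold change -3.36), as were 7 of 8 zona glomerulosa genes (median -1.78), with 12 and 7 when adjusted over the list alone. The set test camera gave adjusted p = 5.34e-15 and 4.08e-07 for these lists, and 0.192 and 0.0891 with an estimated correlation. Counts of 3 list genes or fewer, here and for the other groups, could move by 1 or more genes when a single library was left out. Mitochondrial transcripts took 2.91 to 4.12% of counts in these cKO libraries and 4.04 to 4.88% in their controls. Of 12 Wnt/beta-catenin targets, 7 fell and 1 rose, with the same counts adjusted over the list alone (median -1.32; camera adjusted p = 0.00033, and 0.29 with an estimated correlation). Lgr5 fell 11-fold (-3.46 ± 0.26) and Apcdd1 5.96-fold (-2.58 ± 0.19). Axin2, a common readout of Wnt signalling, was at 55.1 ± 12.9 against 55 ± 4.65 CPM (0.00 ± 0.13, adjusted p = 0.994). Steroidogenic genes moved both ways, with 4 of 15 higher and 2 lower over all genes and over the list alone (camera adjusted p = 0.589). Nr5a1, which encodes SF1 itself, rose 1.76-fold (0.81 ± 0.15), Star, the cholesterol carrier of steroid synthesis, fell 1.65-fold (-0.72 ± 0.20). The 11-beta-hydroxylase gene Cyp11b1 was at 8433 ± 707 against 8012 ± 1246 CPM (adjusted p = 0.709). Of the 19 cholesterol synthesis and uptake genes 9 fell, 11 over the list alone, and none rose, led by Fdps at 3.04-fold lower (-1.60 ± 0.23; camera adjusted p = 0.00276, and 0.555 with an estimated correlation). Endothelial genes fell in 9 of 11 cases and rose in 1, 10 and 1 over the list alone (median -0.353; camera adjusted p = 0.00314, and 0.341 with an estimated correlation). Fibroblast and capsule genes fell in 8 of 12, 9 over the list alone (median -0.892; adjusted p = 0.000314, and 0.432 with an estimated correlation), among them Postn at 4.25-fold lower (-2.09 ± 0.21).

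Macrophage genes were already higher at 6 weeks in females, with 12 of 21 up and 1 down, also over the list alone (median 0.688; camera adjusted p = 0.00696, and 0.626 with an estimated correlation). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, stood at 107 ± 140 against 0.638 ± 0.524 CPM, and Trem2, a lipid-sensing receptor, rose 3.61-fold (1.85 ± 0.35). This count rested partly on 1 library: without cKO replicate 4, 5 macrophage genes were higher. The cyclin-dependent kinase inhibitor gene Cdkn2a rose 2.61-fold (1.39 ± 0.22, adjusted p = 2.61e-05). Cdkn1a was at 40.1 ± 19.4 against 29.6 ± 2.48 CPM (log2 fold change 0.44, adjusted p = 0.112, which became 0.60 with adjusted p = 0.0256 without cKO replicate 1 and 0.61 with adjusted p = 0.0306 without cKO replicate 2). The proliferation marker Mki67 was at 53.7 ± 20.6 against 45.1 ± 5.95 CPM (adjusted p = 0.641). Of 24 cell cycle genes 3 rose and none fell, also over the list alone (Tyms, Mcm7 and Pcna; camera adjusted p = 0.069), and Tyms rose 1.39-fold (0.48 ± 0.11). A total of 6220 of 18645 tested genes differed between genotypes at this age by edgeR's quasi-likelihood test, 2652 higher and 3568 lower in the cKO, and 319 and 2042 of them by at least 2-fold.

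At 9 and 12 weeks genes of the same 3 parts of the female gland were lower in the cKO. Chga fell 10.5-fold at 9 weeks and 8.72-fold at 12 weeks (log2 fold change -3.39 ± 0.27 and -3.12 ± 0.27, n = 4 per group). Kcnk9 fell 4.43-fold and 3.37-fold (-2.15 ± 0.18 and -1.75 ± 0.18), and Lgr5 fell 8.65-fold and 7.86-fold (-3.11 ± 0.26 and -2.98 ± 0.25). Cyp11b2 was at 85.2 ± 69.6 against 224 ± 52.3 CPM at 9 weeks, where cKO replicate 3 set much of the spread (log2 fold change -1.40, and -2.15 without it), and at 91.6 ± 6.64 against 345 ± 97 CPM at 12 weeks (-1.91 ± 0.36, adjusted p = 0.000376). Akr1c18 was lower at both ages, with 195 ± 126 against 977 ± 423 CPM at 9 weeks and 76.6 ± 66 against 1512 ± 1007 CPM at 12 weeks. The X-zone list had 2 genes lower at each age, but 1 at 9 weeks without any one of 5 libraries. Mgat4c was higher at both ages, with 345 ± 158 against 24.1 ± 7.19 CPM and 242 ± 57 against 19.2 ± 3.28 CPM. All 12 medulla genes fell at each age, also over the list alone (camera adjusted p = 8.35e-14 and 5.24e-17, and 0.217 and 0.15 with an estimated correlation). The zona glomerulosa list had 7 and then 6 of 8 genes lower, also over the list alone (medians -1.21 and -0.752; camera adjusted p = 2.31e-05 and 0.00023, and 0.14 and 0.217 with an estimated correlation). Of 12 Wnt targets 7 and then 6 fell and 1 rose at each age, 9 and 7 lower over the list alone (camera adjusted p = 0.00069 and 0.00777, and 0.308 and 0.419 with an estimated correlation).

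Macrophage genes were higher in the older cKO females too. At 9 weeks 15 of 21 rose and 1 fell, 17 and 2 over the list alone (median 1.02), and at 12 weeks 11 rose and none fell, 12 over the list alone (median 0.673). Camera gave adjusted p = 3.45e-05 and 9.76e-05, and both became adjusted p = 0.432 with an estimated correlation. Lyz2, the lysozyme gene of macrophages, rose 2.94-fold and 3.37-fold (1.55 ± 0.30 and 1.75 ± 0.30), and Trem2 rose 2.84-fold and 3.56-fold (1.50 ± 0.34 and 1.83 ± 0.34). Gpnmb reached 252 ± 128 against 8.58 ± 6.6 CPM at 12 weeks. Cdkn2a rose 2.76-fold and 2.02-fold (1.46 ± 0.22 and 1.02 ± 0.21), and Nr5a1 1.7-fold and 1.95-fold (0.77 ± 0.15 and 0.97 ± 0.15). Endothelial genes fell in 10 of 11 cases and rose in 1 at 9 weeks, also over the list alone (median -0.46; camera adjusted p = 0.000326, and 0.251 with an estimated correlation), with Kdr, the main VEGF receptor, 1.56-fold lower (-0.64 ± 0.11). Fibroblast and capsule genes fell in 11 of 12 at that age, also over the list alone (median -1.12; camera adjusted p = 0.000108, and 0.409 with an estimated correlation). The 1 endothelial rise was lost without control replicate 1 or 4 or cKO replicate 1 or 2. At 12 weeks 4 endothelial genes fell and 1 rose (median -0.154; camera adjusted p = 0.212), with 2 lower without control replicate 4 or cKO replicate 1. Fibroblast and capsule genes fell in 9 cases at 12 weeks, or 4 without control replicate 4 (median -0.802; camera adjusted p = 0.000522, and 0.432 with an estimated correlation). Of 24 cell cycle genes 3 fell and none rose at each of these ages, 2 over the list alone (medians -0.49 and -0.521; camera adjusted p = 0.161 and 0.00777, and 0.869 and 0.789 with an estimated correlation). Without single libraries these counts ran from 1 to 5 at 9 weeks (1 without control replicate 4 or cKO replicate 2, 5 without cKO replicate 1). At 12 weeks they ran from 1 to 10 (1 without control replicate 2 or 3 or cKO replicate 1, 10 without cKO replicate 3). The liver transcript Alb was at 287 CPM in cKO replicate 2 at 12 weeks and between 10.3 and 14.7 CPM in cKO replicates 1 and 2 at 9 weeks and 4 at 12 weeks. A total of 6450 genes differed at 9 weeks (2728 higher, 3722 lower) and 4675 at 12 weeks (1699 higher, 2976 lower).

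**Figure D1:**
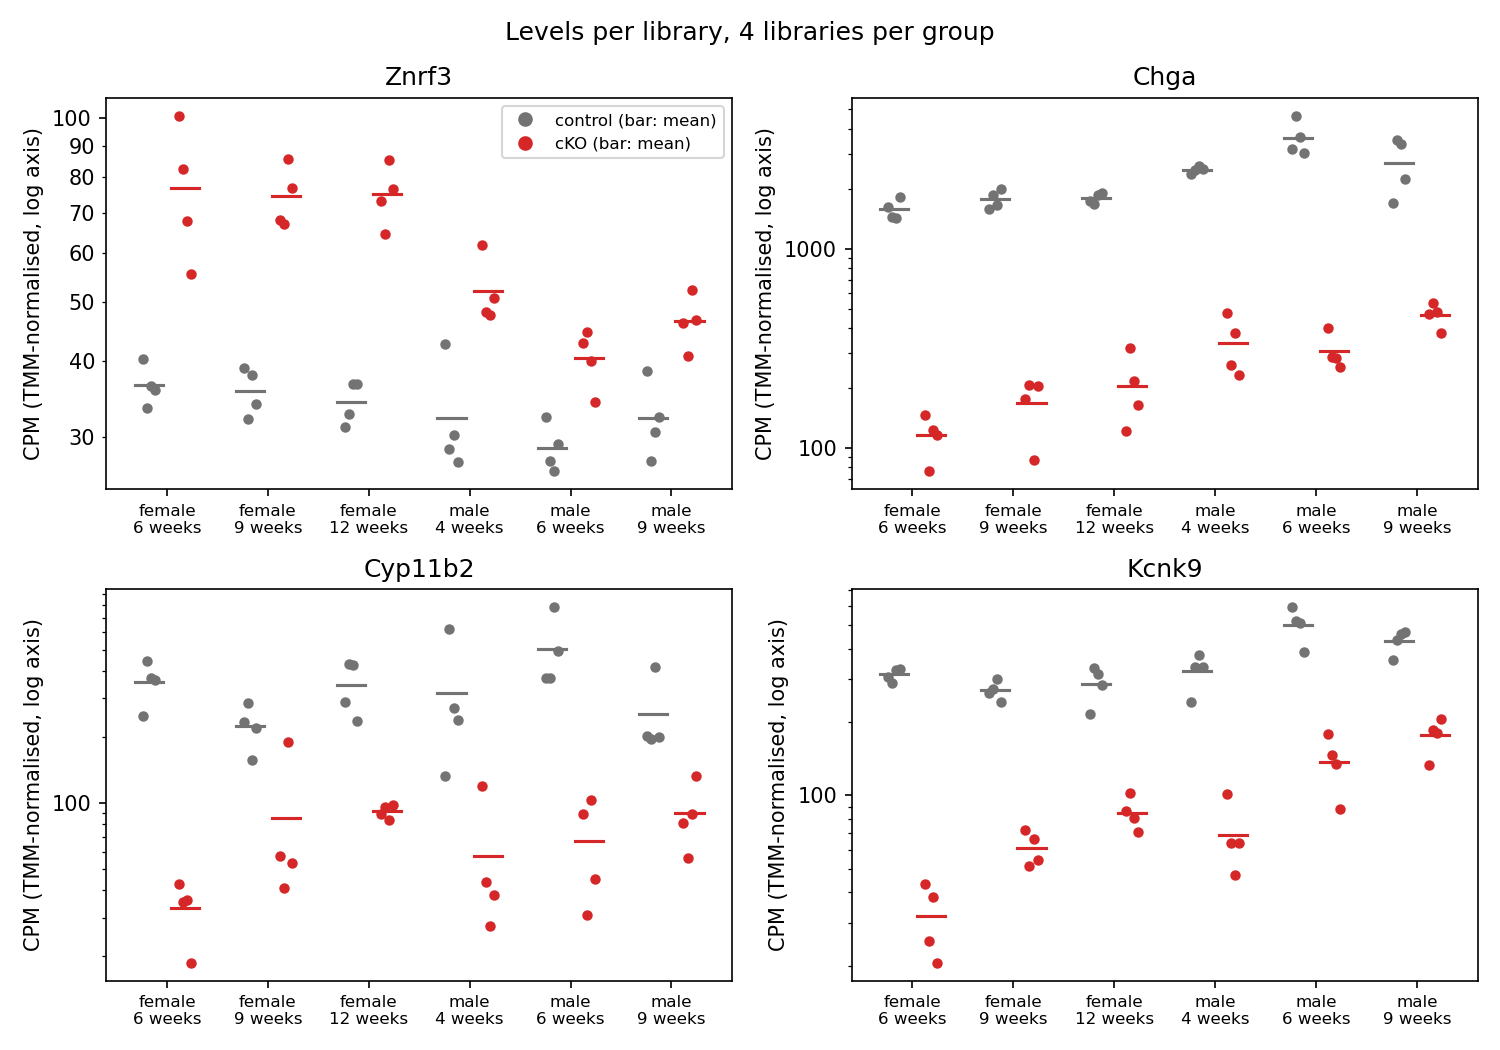
Normalised CPM (log axis) of Znrf3, Chga, Cyp11b2 and Kcnk9 in each library of the 6 age and sex groups, controls in grey and cKO in colour, with the group mean as a bar. Chga lies lower in all 4 cKO libraries than in all 4 controls in each of the 6 comparisons, for example 116 ± 29.4 against 1582 ± 182 CPM in females at 6 weeks, while Znrf3 lies higher.

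In male glands at 4 weeks, the youngest group, medulla, outer cortex and Wnt target genes were already lower in the cKO. Chga fell 7.41-fold (336 ± 113 against 2493 ± 100 CPM, n = 4 per group; log2 fold change -2.89 ± 0.24), Lgr5 fell 7.29-fold (-2.87 ± 0.26), Kcnk9 4.66-fold (-2.22 ± 0.22) and Igfbp6, a secreted growth factor binding protein, 3.61-fold (-1.85 ± 0.21). Col4a6, a basement membrane collagen gene, rose 5.23-fold (2.39 ± 0.36). All 12 medulla genes fell, also over the list alone (median -2.51; camera adjusted p = 2.28e-17, and 0.123 with an estimated correlation). So did 6 of 8 zona glomerulosa genes, 7 over the list alone (median -0.981; adjusted p = 8.53e-06, and 0.0891 with an estimated correlation). Of 12 Wnt targets, 8 fell and 2 rose, 8 and 3 over the list alone (median -1.14; adjusted p = 0.00187, and 0.352 with an estimated correlation). Of 12 fibroblast and capsule genes 6 fell, 8 over the list alone (median -0.883; adjusted p = 7.2e-06, and 0.308 with an estimated correlation). Of 21 macrophage genes 1 was called higher, C1qb, and 1 lower, and the count of higher ones depended on single libraries: it was 5 without control replicate 1, 9 without cKO replicate 1, 4 without cKO replicate 3 and 0 without any one of the other 5. The lower one lost its call without control replicate 3 or 4 or cKO replicate 1. Trem2 was at 6.53 ± 3.59 against 6.74 ± 2.5 CPM (adjusted p = 0.935) and Mmp12 at 7.51 ± 2.54 against 5.59 ± 2.84 CPM (adjusted p = 0.648). Akr1c18 was at 264 CPM in control replicate 2, between 0.623 and 2.02 CPM in the other controls and at 0.0254 ± 0.0345 CPM in cKO glands. The liver transcript Alb was at 71 CPM in cKO replicate 2. Mitochondrial transcripts took 3.03 to 3.65% of counts in cKO libraries and 3.82 to 4.73% in controls. A total of 3275 of 17086 tested genes differed, 1075 higher and 2200 lower, or 32.8% higher, against 42.2% higher by DESeq2. Library numbers above 24 were held by 3 of the 4 controls and by no cKO library, and the count was 1011 with numbers up to 24 only, 4 cKO libraries against 1 control, which is assumed to vary like the other groups, so this count says little about library number.

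At 6 weeks in males macrophage genes were strongly higher in the cKO. Mmp12, a macrophage elastase (chromosome 9, 7344381 to 7369499), was at 304 ± 155 against 9.46 ± 1.91 CPM (n = 4 per group). It was counted in the list of senescence-associated secretory genes, not in the macrophage list. The galectin gene Lgals3 was at 321 ± 163 against 17.2 ± 2.66 CPM, Gpnmb at 378 ± 281 against 1.56 ± 0.485 CPM, and the lysosomal macrophage marker Cd68 rose 5.04-fold (2.33 ± 0.40). Of 21 macrophage genes 14 rose and 1 fell, 18 and 1 over the list alone (median 1.14; camera adjusted p = 3.61e-09, and 0.341 with an estimated correlation). Phagocytosis and lysosome genes rose in 6 of 15 cases, 8 higher and 1 lower over the list alone (median 0.465; adjusted p = 0.00153, and 0.532 with an estimated correlation). The endothelial marker Pecam1 rose 1.62-fold (0.69 ± 0.13) and Plvap 1.84-fold (0.88 ± 0.17). As a list, 5 of 11 endothelial genes rose, also over the list alone, or 3 without control replicate 2 (median 0.21; adjusted p = 0.00219, and 0.432 with an estimated correlation). Medulla genes again fell in all 12 cases, also over the list alone (median -3.19; adjusted p = 3.14e-21, and 0.0891 with an estimated correlation), with Chga at 306 ± 64.9 against 3608 ± 739 CPM. Cyp11b2 was at 66.9 ± 34.6 against 506 ± 194 CPM. Control replicate 2 held 1460 CPM of the medulla transcript Th and the other controls 305 to 539 CPM. The liver transcript Alb was at 45.4 CPM in cKO replicate 2, and mitochondrial transcripts took 3.68 to 4.44% of counts in cKO libraries and 5.16 to 6.02% in controls. A total of 3435 genes differed, 1399 higher and 2036 lower. All 4 controls had library numbers above 24 and all 4 cKO libraries lower ones, so number and genotype cannot be told apart at this age, and with the number range as a covariate across male groups the count was 1613.

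In 9-week males, the oldest male group, macrophage genes were again strongly higher. Mmp12 stood at 586 ± 381 against 16.7 ± 5.52 CPM (n = 4 per group), Lgals3 at 638 ± 429 against 25.6 ± 6.9 CPM, Gpnmb at 692 ± 729 against 5.21 ± 3.09 CPM and Cd68 at 204 ± 132 against 22.9 ± 2.47 CPM. The proton pump subunit gene Atp6v0d2 was at 107 ± 84.9 against 0.595 ± 0.515 CPM, and the inflammatory cytokine gene Il1a rose 13.1-fold (3.71 ± 0.63). Of 21 macrophage genes 15 rose and none fell, also over the list alone (median 1.1; camera adjusted p = 1.87e-09, and 0.341 with an estimated correlation). T and NK cell genes rose in 5 of 13 cases (median 0.892; camera adjusted p = 0.00418, and 0.308 with an estimated correlation), but in 2, 3, 2 and 1 without control replicates 1 and 4 and cKO replicates 3 and 4. B and plasma cell genes rose in 2 of 8 (median 0.575; camera adjusted p = 0.161), neutrophil genes in 1 of 5 (median 0.785; camera adjusted p = 0.166) and antigen presentation genes in 1 of 13 (median 0.243; camera adjusted p = 0.109), with none lower and the same counts over each list alone. Secreted factors associated with senescence rose in 14 of 25 cases and fell in 1, 17 and 2 over the list alone (median 1.04; adjusted p = 1.24e-05, and 0.217 with an estimated correlation). Mmp12 was counted among these factors, so the macrophage and secreted factor rises need not be separate. Phagocytosis genes rose in 9 of 15 and fell in 1, 11 and 1 over the list alone (median 0.643; adjusted p = 0.000314, and 0.464 with an estimated correlation). Both number ranges held 2 cKO and 2 control libraries: macrophage genes were higher in 6 cases with numbers up to 24 and in 14 with numbers above 24, and secreted factors in 4 and 14. The liver transcript Alb was at 62.2 CPM in cKO replicate 3. Senescence markers themselves did not pass the test, with Cdkn2a at 3.53 ± 1.23 against 2.51 ± 0.97 CPM (adjusted p = 0.283) and Cdkn1a at 22.5 ± 8.11 against 18.5 ± 4.46 CPM (adjusted p = 0.415). The apoptosis gene Bax rose 1.61-fold (0.69 ± 0.10). Medulla genes fell in all 12 cases, also over the list alone (median -2.51; adjusted p = 2.49e-17, and 0.123 with an estimated correlation), and Lgr5 fell 6.39-fold (-2.67 ± 0.26). A total of 4110 genes differed, 1779 higher and 2331 lower. The count was 1205 with numbers up to 24 and 2977 with numbers above 24.

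Whether the genotype effect changed with age was tested directly as an interaction of genotype and age. In females, few single genes passed. From 6 to 9 weeks 12 genes had a more positive cKO effect and none a more negative one. Pik3c2g, the X-zone marker, moved by 4.26 ± 0.67 on the log2 scale (adjusted p = 0.0128), and the other X-zone marker Akr1c18 by 4.19 ± 1.01 (adjusted p = 0.157, and 0.00508 by DESeq2). The count was 1258 at an unadjusted p under 0.05 and 93 by DESeq2. It rested on the particular libraries, at 20 without 6-week control replicate 2, at 6 without 6-week control replicate 1 or 9-week cKO replicate 3, and at 5 without 6-week control replicate 3 or 4, 6-week cKO replicate 2 or 3, 9-week control replicate 1, 2 or 4, or 9-week cKO replicate 4. From 9 to 12 weeks edgeR called 0 genes, with 1664 at an unadjusted p under 0.05 and 59 by DESeq2, and 1 and 2 genes without 9-week cKO replicate 1 and 12-week cKO replicate 4. As a list, the zona glomerulosa deficit was smaller at 12 than at 6 weeks, a span added after seeing the data. List tests of the added spans were adjusted apart from the planned ones. Of 8 genes, 2 passed over all genes and 7 over the list alone (median 1.2; camera adjusted p = 8.71e-10, and adjusted p = 0.0213 with an estimated correlation), with Kcnk9 moving by 1.55 ± 0.25 (adjusted p = 0.0119). Without 12-week control replicate 3 or 12-week cKO replicate 4, 4 of these genes passed. Cholesterol synthesis genes had a median shift of 0.625 from 6 to 9 weeks, with none of 19 past the threshold over all genes and 10 over the list alone (camera adjusted p = 5.34e-15, and 0.123 with an estimated correlation). The 24 cell cycle genes had a median shift of -0.682 with 0 passing either way (camera adjusted p = 8.28e-11, and 0.419 with an estimated correlation).

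In males, the matrix-degrading enzyme gene Mmp12 was the only gene whose genotype effect changed from 4 to 6 weeks by edgeR (4.60 ± 0.73, adjusted p = 0.0361), with 1505 genes at an unadjusted p under 0.05 and 98 by DESeq2. The count depended on each library: it was 3 without 4-week control replicate 2 or 4-week cKO replicate 2, 4 without 6-week control replicate 1, 5 without 6-week cKO replicate 3, 0 without any one of the other 12, and 0 without the libraries that held liver transcripts. In these fits without a call the log2 change of Mmp12 stayed between 4.33 and 4.75. As groups, 9 of 11 endothelial genes moved up over the list alone and 0 over all genes (median 0.545; camera adjusted p = 2.08e-11, and 0.0891 with an estimated correlation). Macrophage genes moved up in 7 of 21 over the list alone and 0 over all genes (median 0.507; adjusted p = 6.49e-09, and 0.341 with an estimated correlation). From 6 to 9 weeks edgeR called 0 genes, with 2510 at an unadjusted p under 0.05 and 128 by DESeq2, and 2, 1 and 21 genes without 6-week control replicates 1 and 4 and 9-week cKO replicate 1. Over the added span from 4 to 9 weeks 840 genes passed, 503 with a more positive and 337 with a more negative effect. Mmp12 moved by 4.72 ± 0.72 (adjusted p = 0.00311) and Gas6, a ligand that bridges dying cells to phagocytes, by 1.10 ± 0.17 (adjusted p = 0.00311), from lower in the cKO at 4 weeks (-0.85 ± 0.12). With library numbers up to 24 only, which leaves 1 control at 4 weeks, the changes were 4.64 ± 0.89 and 0.94 ± 0.25, with wider errors and no call (adjusted p = 0.116 and 0.282). The count of 840 was 13 with the library number range as a covariate, 2 with numbers up to 24, 247 without the libraries that held liver transcripts. It lay outside 1.5 times its value without 4-week control replicate 3 (454) or 4 (383), 4-week cKO replicate 3 (462) or 4 (538), 9-week control replicate 1 (290) or 2 (1429), or 9-week cKO replicate 1 (2181), 2 (535) or 3 (334).

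**Figure D2:**
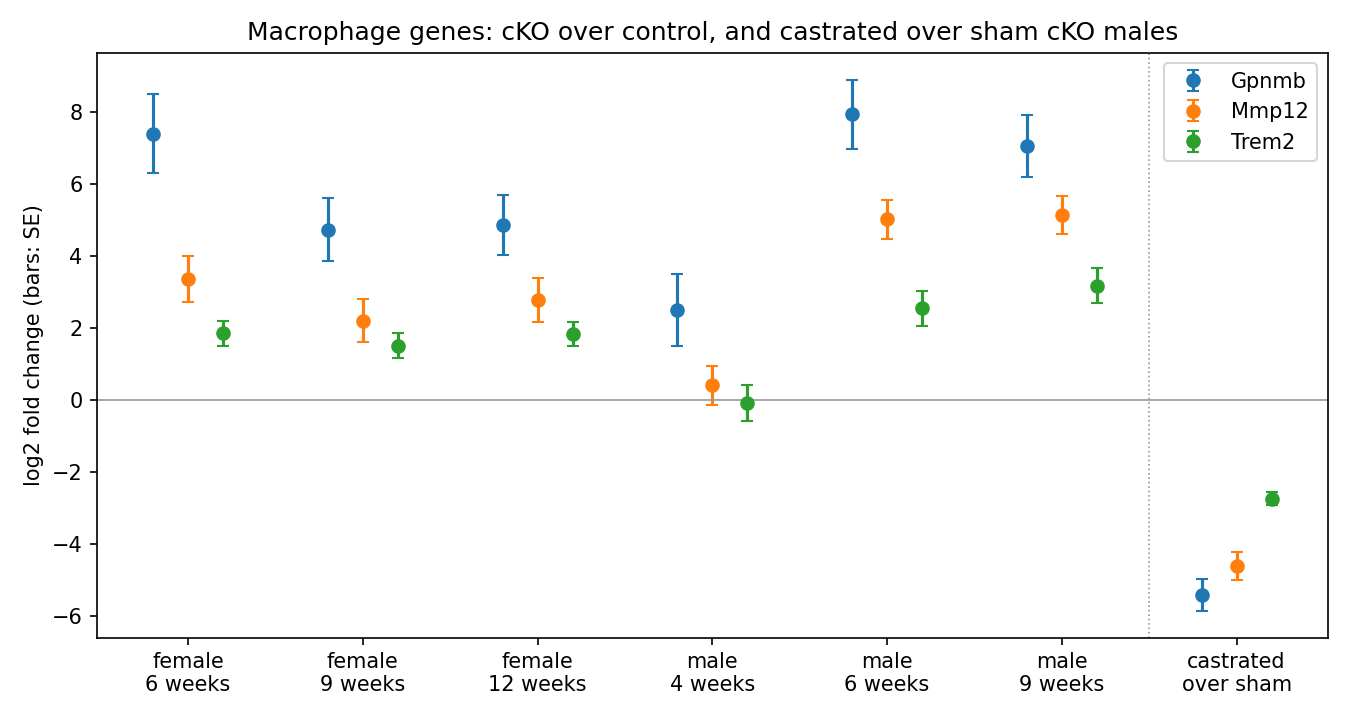
Log2 fold change of cKO over control (points, bars ± SE) for Gpnmb, Mmp12 and Trem2 in the 6 age and sex groups, and of castrated over sham cKO males, 4 libraries per group. In males Mmp12 goes from 0.41 ± 0.53 at 4 weeks to 5.01 ± 0.53 at 6 weeks and 5.13 ± 0.52 at 9 weeks, and castrated cKO males lie at -4.59 ± 0.39.

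Female and male genotype effects were then compared at the ages sampled in both sexes, as an interaction of genotype and sex. Several genes had effects of opposite sign. Mgat4c rose in cKO females at 6 weeks (4.68) and fell in cKO males (-3.34), a difference of -8.02 ± 0.79 (male minus female, adjusted p = 5.41e-05), and at 9 weeks the effects were 3.84 and -2.62 (difference -6.47 ± 0.52, adjusted p = 7.76e-06). Cdh13, which encodes T-cadherin, rose in females by 1.84 at 6 weeks and 2.96 at 9 weeks, was at -1.84 and -1.15 in males, and differed by -3.70 ± 0.34 and -4.13 ± 0.33. Endothelial genes went the other way at 6 weeks: Pecam1 was at -0.27 in females and 0.69 in males (difference 0.94 ± 0.10, adjusted p = 8.06e-05) and Tie1, a receptor of vessel walls, at -0.37 and 0.43 (difference 0.78 ± 0.10). Of 11 endothelial genes 7 had a higher male effect, 10 over the list alone (median 0.608; camera adjusted p = 8.18e-10, and 0.0891 with an estimated correlation). At 9 weeks Nr0b1, a nuclear receptor that restrains SF1, was at 0.76 in females and -0.83 in males, where the fall was not called (adjusted p = 0.247, and 0.0149 with only these 2 groups in the fit; difference -1.61 ± 0.23, adjusted p = 0.00136), and the scavenger receptor gene Cd36 at -0.72 and 1.73 (difference 2.44 ± 0.37). Among these male effects, Cd36 at 9 weeks was 1.29 with library numbers up to 24 (adjusted p = 0.124), Cdh13 at 9 weeks -0.99 with numbers above 24 (adjusted p = 0.0629) and Tie1 at 6 weeks 0.31 with the number range as a covariate (adjusted p = 0.229). Cholesterol synthesis genes had a lower male effect in 7 of 18 cases, 12 over the list alone (median -0.607; camera adjusted p = 4.35e-08, and 0.341 with an estimated correlation). A total of 1349 genes differed between the sexes in their genotype effect at 6 weeks, 898 with a higher male effect, and 1547 at 9 weeks, 960 with a higher male effect. The 9-week split of 62.1% higher was 51.1% by DESeq2, 47.3% without the libraries that held liver transcripts and 34.5% with all 48 libraries in the fit, so the direction of the majority is not settled. The 9-week count was 243 with male library numbers up to 24, 1030 without female cKO replicate 3, 965 without male control replicate 1 and 2356 without male cKO replicate 1. The sexes were held in separate count tables, so table and sex could not be told apart and only genotype effects were set against each other. At 6 weeks all male controls had library numbers above 24 and all male cKO libraries lower ones. An effect of library number in males therefore cannot be told apart from the sex difference at that age.

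Castrated and sham-operated cKO males were compared at 9 weeks. Several genes that were nearly absent in sham-operated cKO males appeared in castrated ones. Akr1d1, a steroid 5-beta-reductase gene (chromosome 6, 37530173 to 37568815), was at 2964 ± 783 against 0.0688 ± 0.104 CPM (mean ± SD, n = 4 per group). Akr1c18 was at 44.8 ± 47.8 against 0.0233 ± 0.0277 CPM and Pik3c2g at 9.89 ± 11 against 0.0153 ± 0.019 CPM, and the sham values of all 3 rested on few or no counts. Oxtr, the oxytocin receptor gene, rose 180-fold (7.50 ± 0.42) and Vnn3, a pantetheinase gene, 144-fold (7.17 ± 0.24). Cited1, a transcriptional co-regulator gene (chromosome X, 102247381 to 102252181), fell 258-fold (66.7 ± 16.1 CPM in sham, 0.263 ± 0.103 CPM in castrated glands) and Acan, the aggrecan gene, 102-fold (-6.68 ± 0.27). Steroidogenic genes rose in 8 of 15 cases and fell in 2, 9 and 2 over the list alone (median 0.5; camera adjusted p = 0.0373, and 0.555 with an estimated correlation). Cyp21a1, the 21-hydroxylase gene, was at 22880 ± 3503 against 7320 ± 1117 CPM. Nr5a1 rose 3.1-fold (1.63 ± 0.15) and Nr0b1 12.1-fold (3.60 ± 0.16). Cholesterol synthesis and uptake genes rose in 17 of 18 cases, also over the list alone (median 1.3; adjusted p = 1.07e-09, and 0.308 with an estimated correlation). All 3 X-zone genes rose, also over the list alone (adjusted p = 0.00292, and 0.308 with an estimated correlation).

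Macrophage genes were lower after castration. Lgals3 fell 16.1-fold (521 ± 39.3 CPM in sham, 32.3 ± 7.42 CPM in castrated glands, n = 4 per group), Cd68 7.43-fold (-2.89 ± 0.14), Trem2 and Mmp12 by -2.73 ± 0.19 and -4.59 ± 0.39 on the log2 scale. Of 21 macrophage genes 18 fell and none rose, also over the list alone (median -1.38; camera adjusted p = 4.21e-08, and 0.432 with an estimated correlation). So did 20 of 26 secreted factors associated with senescence, also over the list alone (median -1.6; adjusted p = 6.44e-08, and 0.0891 with an estimated correlation), and 9 of 13 antigen presentation genes, 11 over the list alone (median -0.873; adjusted p = 0.000655, and 0.52 with an estimated correlation). Mmp12 was counted among the secreted factors, not among the 21 macrophage genes. Other lists moved down too. All 12 medulla genes fell (median -1.5; adjusted p = 0.000309, and 0.555 with an estimated correlation), and so did 8 of 8 zona glomerulosa genes (median -1.22; adjusted p = 9.7e-05, and 0.251 with an estimated correlation). Of 11 endothelial genes 10 fell, 11 over the list alone (median -0.602; adjusted p = 0.000432, and 0.435 with an estimated correlation), and 10 of 12 fibroblast genes while 1 rose (median -1.08; adjusted p = 0.000178, and 0.251 with an estimated correlation). Where no second count is given, it was the same over the list alone. Of 11 Wnt targets 8 fell and 1 rose, also over the list alone (median -1.08; adjusted p = 0.0026, and 0.18 with an estimated correlation). Cell cycle genes rose in 14 of 24 cases, 14 with 1 lower over the list alone and 9 without castrated replicate 3 (median 0.589; adjusted p = 0.000925, and 0.595 with an estimated correlation), with Ccna2 and Ccnb1 at 1.24 and 1.66 on the log2 scale.

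The remaining fixed lists in castrated glands are given with counts as higher and lower and camera's adjusted p. Gonad-type steroidogenic genes had 0 and 3 of 5 (camera adjusted p = 0.101), p53 targets 3 and 2 of 15 (camera adjusted p = 0.659), interferon-stimulated genes 3 and 2 of 15 (camera adjusted p = 0.838), and phagocytosis genes 2 and 7 of 16 (camera adjusted p = 0.166). T and NK cell genes had 0 and 4 of 14, 3 lower over the list alone (camera adjusted p = 0.0901), B cell genes 1 and 1 of 8 (camera adjusted p = 0.742), and neutrophil genes 0 and 2 of 4, 3 lower over the list alone (camera adjusted p = 0.132). Schwann cell genes had 2 and 4 of 6 (camera adjusted p = 0.593), adipose genes 0 and 2 of 6 (camera adjusted p = 0.22), and erythrocyte genes 0 and 5 of 5 (camera adjusted p = 0.0477, and 0.501 with an estimated correlation). Leaving out castrated replicate 2 or sham replicate 4 left 3 erythrocyte genes lower, and leaving out sham replicate 3 left 1 gonad-type gene. A total of 7402 of 16961 tested genes differed, 3363 higher and 4039 lower in castrated glands (45.4% higher). With library totals as the scale, an alternative added later that moved the median over all genes to -0.209, the calls were 1687 and 5326 (24.1% higher). The count was 6465 with the 6 libraries numbered up to 24 only. Scaling factors ran from 0.907 to 0.946 in castrated and from 1.02 to 1.11 in sham libraries, and mitochondrial transcripts took 3.55 to 4.44% of counts in castrated glands, 2.41 to 3.11% in 3 sham glands and 9.87% in sham replicate 1. Without a filter on low counts the median log2 fold change over all genes was -0.109.

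**Figure D3:**
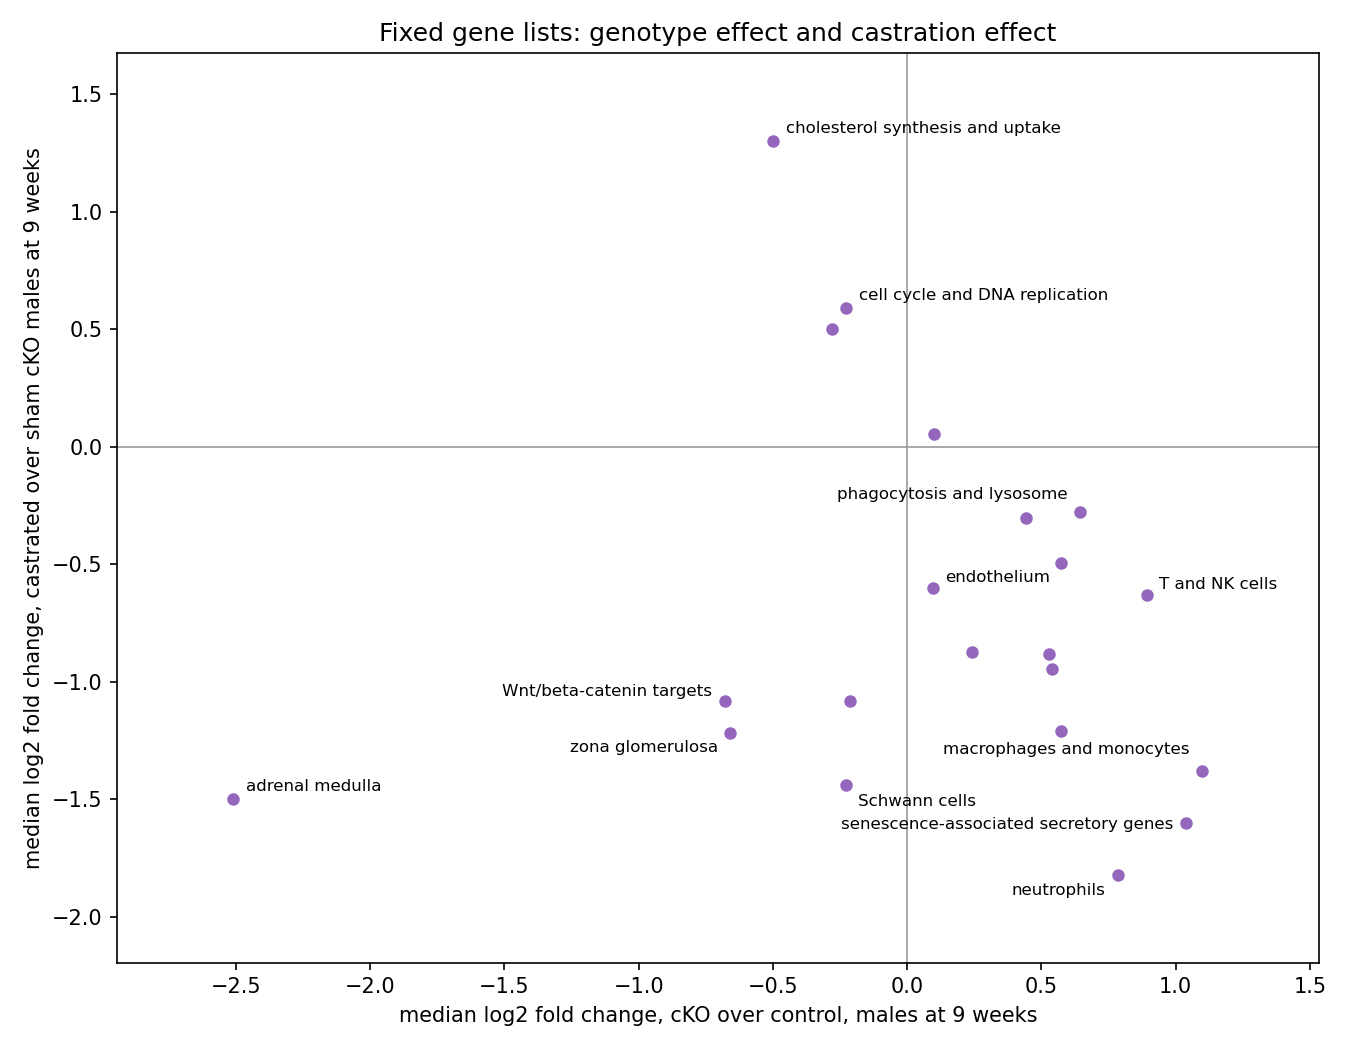
Median log2 fold change of the fixed gene lists other than the X-zone list, of whose 3 genes Akr1c18 and Pik3c2g had few or no counts in all of these males but the castrated ones, for castrated over sham cKO males at 9 weeks (4 libraries each) on the vertical axis against cKO over control males at 9 weeks (4 libraries each) on the horizontal axis. Each point is a list, and the macrophage list lies at 1.1 on the horizontal and -1.38 on the vertical axis, the cholesterol list at -0.499 and 1.3, and the medulla list at -2.51 and -1.5. In cKO over control males 10 cholesterol genes were called lower, a count that ran from 3 to 12 without single libraries.

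Genes changed in all 6 genotype comparisons were counted among the 16971 genes tested in each. A total of 130 were higher in all 6 cKO groups (0.0207 for independent lists), 1027 were lower in all 6 (0.244 for independent lists), 387 were called in opposite directions and 6618 in none. Those lower included the 12 medulla genes, the Wnt targets Lgr5, Lef1, Nkd1, Ccnd1 and Apcdd1, the zona glomerulosa genes Kcnk9 and Agtr1b, and the Schwann cell genes Sox10 and S100b. Those higher included Znrf3, which is on none of the lists, and the complement gene C1qb, the only list member higher in all 6. Wnt targets fell in 6 of 12 cases at 6 weeks in males and 7 at 9 weeks, 7 and 8 over the list alone, with 1 and 0 higher (camera adjusted p = 0.00741 and 0.000412, and 0.432 and 0.308 with an estimated correlation). Zona glomerulosa genes fell in 5 and 4 of 8, also over the list alone (adjusted p = 9.76e-05 and 0.00627, and 0.0891 and 0.229 with an estimated correlation). Across genes, which are not independent replicates, the log2 fold changes of pairs of genotype comparisons correlated with r from 0.609 (males at 4 and 9 weeks) to 0.823 (females at 6 and 9 weeks). From 94.2 to 100% of genes called in both had the same direction. The castration effect was set against the genotype effects in the same way. Against cKO males at 9 weeks 47.4% of genes called in both moved the same way (r = -0.0873): 697 genes were higher in the cKO and lower after castration against 421 for independent lists, and 848 were lower in both against 515. Those lower in the cKO and higher after castration numbered 418 against 429, and 156 were higher in both against 350. Against cKO females at 9 weeks 91.3% moved the same way (r = 0.419), with 1290 higher and 2091 lower in both against 536 and 776. The share was 88.7% and 88.6% for cKO females at 6 and 12 weeks. For cKO males it was 91.1% at 4 weeks (r = 0.335) and 62.6% at 6 weeks (r = 0.0481). A high share was thus not particular to females.

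Over all lists, camera with its preset correlation called 109 of 286 planned pairs of list and comparison, and fry called 89. Camera with an estimated correlation called 0 of these, so the camera results of the planned comparisons rest on the preset correlation. The added zona glomerulosa test from 6 to 12 weeks is not among these pairs and was adjusted only with the lists of the added spans.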

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

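The tests chosen only after the results were seen were those that set endothelial against medulla genes, macrophage against other blood cell genes and the castration calls with library totals as the scale, the span comparisons of the first with the last age, and the fits by library number or without libraries that held liver transcripts.

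All 12 medulla genes were lower in the libraries labelled cKO in all 6 genotype comparisons, and dilution and library number were tested as technical explanations. A dilution of all other cells alike by cortical cells would lower endothelial genes by as much. Their median lay above the medulla median by 2.3 (males at 4 weeks) to 3.4 (males at 6 weeks) on the log2 scale. More vessels in the cKO gland could hide such a dilution, so the gap does not exclude it. Fibroblast and capsule genes were called lower as well, from 3 members in males at 9 weeks to 11 in females at 9 weeks. Within each range of library numbers at 9 weeks in males all 12 members were negative, which library number as the source would not give. In females, whose numbers follow the groups, and in males at 6 weeks, number and genotype cannot be told apart. Dilution of an unchanged medulla, fewer medulla cells per gland and lower transcript levels per cell all stay open and were not separated here. A count of medulla cells on sections would help to separate them.

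Macrophage genes were higher in cKO males at 6 and 9 weeks, with 14 and 15 of 21 called. Liver tissue with its own macrophages in the libraries of high Alb does not account for it, since 15 members at 6 weeks and 14 at 9 weeks were called without those libraries. The 9-week fit still held cKO replicate 2, with lower levels of liver transcripts (Alb 4.04 and Apoa1 1.93 CPM). Library number does not account for it at 9 weeks, since 17 of 21 members were positive with numbers up to 24 and 20 above 24, whereas at 6 weeks all controls and no cKO library had numbers above 24, so number and genotype cannot be told apart there. More leukocytes or blood of every kind could not be set aside: the macrophage median lay above those of T and NK cells, neutrophils, B cells and erythrocytes by 0.208, 0.315, 0.525 and 0.526 on the log2 scale, and the smallest of these gaps is too narrow to decide. A rise of macrophages alone stays open beside it, and neither was separated from more transcript per cell, which counts of each cell type by sorting or staining would do.

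Castration of cKO males changed 7402 genes. Sham replicate 1, with the highest mitochondrial share, does not account for them, since 95.7% were called again in the same direction without it. A few abundant genes that set the scale stay open in part: with library totals as the scale 77.4% of the calls were made again in the same direction, and the share of higher calls went from 45.4% to 24.1%, so the balance of rises and falls depends on the scale. With the reporter allele as a covariate, mixed over both groups, 6987 genes passed. The loss of testicular hormones from week 4, which the design names, may lie behind the change, as a hypothesis, since hormone levels are not among these data.

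Other splits of the same libraries were tested for every count of genes. Each genotype effect had 1 of 35 splits as large, the real one. That is the smallest share that 35 splits can give, so it makes chance unlikely but does not exclude it. The counts were 6220 genes against at most 219 in any other split in females at 6 weeks, 6450 against 1 at 9 weeks, 4675 against 186 at 12 weeks. In males they were 3275 against 279 at 4 weeks, 3435 against 1 at 6 weeks and 4110 against 1878 at 9 weeks, where the other split exchanged control replicate 2 and cKO replicate 1. In males at 6 weeks the real split was also the split by library number range. For castration the count was 7402 against 1, again with 1 of 35 splits as large. Sex differences were split by exchanging cKO and control libraries within a sex, which also breaks the genotype effect common to both sexes. Such splits cannot decide whether chance gives a sex difference, and no conclusion is drawn from them. At 9 weeks the real 1547 stood against a highest other of 1053, with 1 of 100 splits as large. At 6 weeks 5 of 100 splits were as large as the real 1349, with a highest other of 3220. Age differences were split by exchanging ages within a genotype, which also breaks the age effect common to both genotypes. Such splits cannot decide whether chance gives a change with age, and no conclusion is drawn from them. For females from 6 to 9 weeks 5 of 100 splits reached the real 12 genes (highest other 166). For females from 9 to 12 weeks (highest other 2) and males from 6 to 9 weeks (highest other 13) the real count was 0. Every split reaches a count of 0 (100 of 100 in both), so these splits decide nothing. For females from 6 to 12 weeks 4 of 100 splits reached the real 60 genes (highest other 292), and for males from 4 to 9 weeks 3 of 100 reached the real 840 (highest other 5879). These shares are under 0.05, but the splits break the common age effect, so nothing is drawn from them. The real counts also ran from 11 to 143 and from 290 to 2181 without single libraries. They were 19 and 254 with the replicate block, and 15 and 343 with only the 4 groups in the fit. Without the libraries that held liver transcripts they were 11 and 247. For males from 4 to 6 weeks the real count of 1 gene was reached by 4 of 100 splits, with a highest other of 996, but it rests on 1 gene that single libraries decide, so nothing is drawn from it. Splits far above the real count point to a structure of the samples. The highest ones for 6 to 9, 6 to 12 and 4 to 9 weeks exchanged all cKO libraries of both ages, which turns the age effect common to both genotypes into a difference. The highest one for sex at 6 weeks exchanged 3 of 4 male controls with 3 of 4 male cKO libraries, which does the same with the common genotype effect. The 996 for males from 4 to 6 weeks came from exchanging control replicates 1 and 2 at 4 weeks with 2 and 3 at 6 weeks.

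Some genes had a genotype effect that differed between ages or sexes by the interaction test, on the log2 scale. Between ages these were Pik3c2g from 6 to 9 weeks in females (4.26), Kcnk9 from 6 to 12 weeks in females (1.55), Mmp12 from 4 to 6 and from 4 to 9 weeks in males (4.60 and 4.72) and Gas6 from 4 to 9 weeks in males (1.10). Between sexes, male minus female, they were Mgat4c (-8.02 at 6 and -6.47 at 9 weeks), Cdh13 (-3.70 and -4.13), Pecam1 and Tie1 at 6 weeks (0.94 and 0.78), and Nr0b1 and Cd36 at 9 weeks (-1.61 and 2.44).

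Groups of 4 libraries were tested for 1 library far from the other 3. With normally distributed values chance gives about 1 in 20 such groups. Levels near 0, such as many of Alb, need not be so distributed, so no excess over chance is drawn. A library lay apart in 20 of 135 groups. Among named genes these were Akr1c18 in female 6-week control replicate 4 (3200 CPM, others 1237 to 1361) and male 4-week control replicate 2 (264, others 0.623 to 2.02), and Pik3c2g in female 6-week cKO replicate 1 (11.9, others 2.01 to 3.01). They were also Mgat4c in female 6-week control replicate 3 (53.1, others 7.86 to 14.4), Gpnmb in female 6-week cKO replicate 4 (317, others 26.2 to 46.1) and Cyp11b2 in female 9-week cKO replicate 3 (189, others 40.9 to 57.5). In males at 9 weeks they were Atp6v0d2 in control replicate 3 (1.36 CPM, others 0.264 to 0.43), Cdkn2a in control replicate 4 (3.96, others 1.92 to 2.22) and Cdkn1a in cKO replicate 4 (34.7, others 17.5 to 19). Total counts stood apart in male 4-week control replicate 1 (24.8M, others 15.8 to 16.1), and the mitochondrial share in sham replicate 1 (9.87%, others 2.41 to 3.11%). Alb stood apart in 9 libraries. In females it was at 287 CPM in female 12-week cKO replicate 2 (others 0.0261 to 10.3), 5.76 in female 6-week cKO replicate 3 (others 0.115 to 0.233) and 3.17 in female 9-week control replicate 4 (others 0.0238 to 0.056). In males it was at 71 in male 4-week cKO replicate 2 (others 0.168 to 1.01), 45.4 in male 6-week cKO replicate 2 (others 0 to 0.151) and 0.437 in male 6-week control replicate 1 (others 0). It was also at 62.2 in male 9-week cKO replicate 3 (others 0 to 4.04), 0.64 in male 9-week control replicate 2 (others 0 to 0.0893) and 18.1 in castrated replicate 3 (others 0.207 to 1.3).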

How the results depend on the processing

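The fits by library number range, without the 4 libraries that held liver transcripts, with library totals as the scale and over the first to last age were chosen only after the data were seen. No called gene named in the text reversed its direction under a setting tried. Over the 139 pairs of a named gene and a comparison, 2080 repeats under other settings kept direction and side of the threshold, 23 lost the call, 5 gained it and 14 changed sign without a call in either fit. Genotype counts kept within 1.5 times under DESeq2, relative log expression scaling, both filters and the fits of 2 groups, with the exceptions given here, and the cause was not tested unless stated. For males at 4 weeks (3275) the count was 1701 with the library number range as a covariate and 1011 with numbers up to 24 only (1 control), for 6 weeks (3435) 1613 with the covariate, and for 9 weeks (4110) 1205 with numbers up to 24, which leaves fewer libraries, against 2977 above 24. Without the libraries that held liver transcripts the counts were 4305 for females at 12 weeks and 2984, 2925 and 2822 for males at 4, 6 and 9 weeks. Changes with age depended most on the processing. Under DESeq2 they were 93 (edgeR 12) for females from 6 to 9 weeks, 59 (0) from 9 to 12 weeks and 285 (60) from 6 to 12 weeks. In males DESeq2 gave 98 (1) from 4 to 6 weeks, 128 (0) from 6 to 9 weeks and 1650 (840) from 4 to 9 weeks. With only the 4 groups in the fit the counts were 42 for females from 6 to 9 weeks, 15 from 6 to 12 weeks, 8 for males from 4 to 6 weeks and 343 from 4 to 9 weeks. Without the libraries that held liver transcripts they were 11 for females from 6 to 12 weeks, 0 for males from 4 to 6 weeks and 247 from 4 to 9 weeks. Males from 4 to 6 weeks gave 2 with no filter on low counts, and males from 4 to 9 weeks gave 13 with the number range as a covariate and 2 with numbers up to 24. The sex difference at 6 weeks (1349) was 2024 by DESeq2. At 9 weeks (1547) it was 2489 by DESeq2, 243 with male numbers up to 24 and 2590 with all 48 libraries in the fit. The share with a higher male effect at 9 weeks (62.1%) was 34.5% with all 48 libraries, 47.3% without the libraries that held liver transcripts and 72.2% with the stricter filter. At 6 weeks (66.6%) it was 79.5% with the stricter filter. The share of higher calls in males at 4 weeks (32.8%) was 42.2% by DESeq2 and 49.6% with the stricter filter, and at 6 weeks (40.7%) 52.9% with that filter, which tests fewer genes. The castration count (7402) was 7482 under relative log expression scaling, 4971 with the stricter filter, 7684 without a filter, 7013 with library totals as the scale (24.1% higher against 45.4%) and 6987 with the reporter allele as a covariate. List tests called 109 pairs with the preset correlation, 89 with fry and 0 with an estimated correlation. Genes shared by all 6 genotype comparisons (1157) were 735 with the stricter filter and 1238 by DESeq2. Leaving out single libraries gave 5391 to 6103, 5446 to 5993 and 3896 to 4466 genes for females at 6, 9 and 12 weeks, and 2609 to 4745, 2806 to 3365 and 2947 to 4403 for males at 4, 6 and 9 weeks. Changes with age ran from 5 to 20, 0 to 2 and 11 to 143 in females (6 to 9, 9 to 12 and 6 to 12 weeks), and from 0 to 5, 0 to 21 and 290 to 2181 in males (4 to 6, 6 to 9 and 4 to 9 weeks). The sex differences ran from 904 to 1519 at 6 weeks and from 965 to 2356 at 9 weeks, and castration from 6189 to 8136. Depth limits low genes most in males, where total counts were lowest.

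Replicate numbers did not pair the samples. Of 24 pairs of a cKO and a control library with the same number, 1 had a correlation of deviations above 0.1 (range -0.253 to 0.107), and 4 correlated best with their own number. With the replicate number as a block the counts were 5446, 5705 and 3981 for females at 6, 9 and 12 weeks and 2692, 2826 and 3341 for males at 4, 6 and 9 weeks. The block gave 19 for females from 6 to 12 weeks, 0 for males from 4 to 6 weeks, 254 from 4 to 9 weeks, 659 for the sex difference at 6 weeks (77.1% higher) and 1253 at 9 weeks. Of the pairs of a named gene and a comparison, 116 kept direction and side of the threshold under the block, called or not, 1 lost its call and 1 changed sign without a call in either fit. Sham libraries carry no distinct replicate numbers, so no block was fitted for castration.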

Other observations

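The test of the listed hepatocyte genes was chosen only after Alb had been seen, and the test of castration against the sex difference was chosen before its result was seen.

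Several lists moved in ways not described among the comparisons. In females at 9 weeks 4 T and NK cell genes were called higher in cKO glands and 0 lower (median 0.804; camera adjusted p = 0.00796), but 1 without control replicate 1, 2 without control replicate 4 or cKO replicate 2, and 8 without cKO replicate 3. Fibroblast and matrix genes had a higher male than female genotype effect at 9 weeks in 9 of 12 cases and 0 lower, 11 over the list alone (median 0.988; adjusted p = 4.35e-06). That count ran from 2 to 10 without single libraries, lowest without male cKO replicate 3. Gonad-type steroidogenic genes differed in 1 case over all genes, with 0 to 2 without single libraries, and in 8 over the list alone (median 2.31; adjusted p = 0.00462). From 9 to 12 weeks in females the cKO effect on interferon-stimulated genes moved down by list (median -0.641; adjusted p = 2.19e-07) with 0 members called. With an estimated correlation none of these list tests passed (adjusted p from 0.226 to 0.52). After castration the phagocyte receptor gene Mertk fell by 1.95 on the log2 scale and the aldose reductase-like gene Akr1b7 fell by 2.91, while the thyroid hormone receptor gene Thrb rose by 2.33.

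Male and female cKO effects that differ at 9 weeks were set against castration, which shares no libraries with them. If testicular hormones set part of the male effect, castration would move these genes in cKO males opposite to the sex difference. No control males with surgery are labelled, so the genotype effect in castrated males is unknown. A response to castration in glands of either genotype could give the same direction. Among genes called in both, 814 of 823 with a higher male effect were lower after castration and 476 of 478 with a lower male effect were higher, 98.9% at the least, against 223 and 117 genes for independent lists. Over DESeq2, a stricter filter, relative log expression scaling and fits without the libraries that held liver transcripts, from 99.1 to 99.5% of such genes went the opposite way. Across genes, which are not independent replicates, both sets of log2 fold changes correlated with r = -0.598. A contribution of testicular hormones to the male effect could give this value of 98.9%, as a hypothesis. Without castrated controls such a contribution cannot be told apart from a castration response in either genotype. The sexes lie in separate count tables, and the sex difference fell to 243 genes with male library numbers up to 24, so which genes differ depends on the libraries used.

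Alb was high in 4 cKO libraries, which may hold RNA from hepatocytes. Of 36 hepatocyte genes listed before the test, 7 in females and 6 in males had a median above 1 CPM in the other libraries. Of the 36, 29 (80.6%) lay above 10 times that median in female 12-week cKO replicate 2 and 23 (63.9%) in each of the 3 male libraries. Alb, Apoa1, Serpina3k, Ttr and Fgb were at 287, 21.4, 15.6, 14.2 and 15.8 CPM in the female library and at 71, 18.5, 10.1, 7.64 and 4.07 CPM in male 4-week replicate 2. Liver RNA and another source of these transcripts cannot be told apart, since genes also present in the gland and low depth in males limit the test. Glands were cleaned of fat by hand, per the labels' protocols, with no sort that would remove other cells.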
